A study of Mus musculus with 8 samples.

How the data were processed

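H3K27me3 chromatin from jejunal crypt epithelial cells of female mice was profiled in 4 control and 4 DKO samples, 7 days after ablation of Kdm6a and Kdm6b. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, chromatin was fixed with formaldehyde and digested with micrococcal nuclease before immunoprecipitation. Per the submitters' processing notes the tools included FastQC 0.10.1, Bowtie 0.12.7, SAMtools 1.11, Picard 1.141, SICER 1.0.3 and edgeR, for which no version is given, with genome build mm10. Their order and settings are not given in the sources used here.

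The data were 1 deposited table of the authors' comparison of the groups, with 378 regions. Per the file headers it holds each region's position, width, number of windows, and counts of windows with a log2 fold change up or down. The authors' deposited p-value and FDR of each region were used as given, and the table's name and column headers are those of csaw, a package that combines window tests into regions. Its version and settings are not given in the sources used here. The deposited log2 fold change of the representative window was the main measure of change, and that of the best window was used as an alternative. The table's counts of windows per region, by direction, are the authors' deposited counts. Many windows are in neither count, as at Mycn, with 26 up and 0 down of 148. The rule for counting a window is not given in the sources used here, so a window outside the counts need not be unchanged. Columns of per-sample values number 0, so no depth, normalization, replicate spread or refit could be examined, and intervals given for shares cover the counting of regions only. The sign of the log2 fold change matched the table's direction in every row. Its reference group is not named. The index of each region's representative window runs through the chromosomes 2 times, as 2 sets of windows would, and regions made of a single window were 1.0 or 2.0 kb wide. The last 3 fields of a row hold gene annotations with unquoted commas, so rows had 17 to 21 cells for 17 columns; entries ending in letters were read as overlaps and entries ending in a distance as flanking genes. The letters P, E and I were read as promoter, exon and intron, as is usual for this layout.

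The FDR values were recomputed from the p-values by the Benjamini-Hochberg method. They were reproduced with 58963 tests to within a relative difference of 5.8e-15, so the table holds the full list at FDR 0.05. Of 333 gene names, 331 matched a symbol, identifier or synonym of the RefSeq genes of GRCm38.p6, the same build. For 10 names the reference position lay over 10 kb from a region: Mir3084-2, carried by 7 regions, Galnt2, carried by 6, Mir692-2, Btbd35f10, Btbd35f20, Fam110b, Rasgef1b, Ccr9, Fkbp5 and Klrb1b. Counts kept the table's assignments, but these names were not used to describe regions in the text unless so stated. Some of them, such as Fkbp5, Ccr9 and Klrb1b, lie within 100 kb of the region, and the authors' annotation can hold longer transcripts than RefSeq.

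The tests were planned before the data were examined. The split of directions was tested with a two-sided exact binomial test and given a 95% Clopper-Pearson interval. Shares in up and down regions were compared with Fisher's exact test, medians and correlations with 100000 random permutations (seed 11), and p-values of one family were adjusted by the Benjamini-Hochberg method. Comparisons of width and of the share of changed windows between directions were added after the data were seen, as were correlations within a direction, promoter shares within width classes and the tests with 1 region per 1 Mb block. A gene counted as lying at a region if the table named it as overlapping or within 5 kb. The test planned for a table with counts per sample could not be run on these values, and the authors' results were described instead. An X chromosome test against assembly length was not run, as chromosome lengths were not used here.

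The text names the 12 regions with the largest positive and the 12 with the largest negative log2 fold change among those assigned a gene, and up to 4 members of each gene list per direction, by lowest FDR. The lists, fixed before the data were examined, were H3K27 and H3K9/H4K20 demethylases, PRC2 subunits, PRC1 subunits, Hox genes, developmental transcription factors, regional gut identity, intestinal stem cell, regenerative or fetal-like epithelium, proliferation, cyclin-dependent kinase inhibitors, Paneth, goblet, enteroendocrine, tuft and enterocyte cells, the Wnt, BMP and TGF-beta, Notch, hedgehog and FGF pathways, immune, stromal and smooth muscle, endothelial, and neuron and glia cells, imprinted genes, X-inactivation and escape genes, antigen presentation and interferon response, and protocadherin clusters.

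Alternatives were FDR 0.01, an absolute log2 fold change of at least 1, regions without windows of both directions, blocks of 1 Mb or 100 kb, autosomes only, wide or narrow regions, 1 region per gene or per 1 Mb block, overlapping genes only, and leaving out names far from their reference position. The functions were tested on simulated data. A list cut at FDR 0.05 returned the 58000 tests it was made with. With 250 and 120 simulated regions, the permutation test of medians gave p under 0.05 in 10 of 200 datasets with no shift and in 194 of 200 with a shift of 0.1 and an SD of 0.2. The permutation test of a rank correlation gave p under 0.05 in 10 of 200 datasets with none and in 200 of 200 with a correlation of 0.25. The values simulated for these permutation tests were independent and not cut at an FDR. The real regions are neither, so these rates check the functions and need not hold for the regions. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.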

Results

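Trimethylation of histone H3 at lysine 27 (H3K27me3), a mark of genes silenced by Polycomb complexes, was measured by chromatin immunoprecipitation and sequencing after micrococcal nuclease digestion. The cells were jejunal crypt epithelial cells of female mice taken 7 days after deletion of Kdm6a and Kdm6b, which encode the H3K27 demethylases UTX and JMJD3. There were 4 control samples and 4 double-knockout (DKO) samples. The question was where loss of both demethylases changes H3K27me3. The values analysed were those of the authors' deposited table, which compares the groups region by region and lists 378 regions with a false discovery rate (FDR) of 0.0498 or lower. The table holds no value per sample, so the depth of each library is unknown, the spread between the 4 replicates of a group cannot be seen, and no fold change carries a standard error. It does not state which group is the reference. Regions are therefore called up or down as the table calls them. Reading up as higher in DKO than in control is the usual convention for such a comparison, not a statement of the table. Windows are also called up or down as counted there. The counts leave out windows by a rule that is not given, so a window outside them need not be unchanged.

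The regions with the largest positive changes lay at Ncald, at the Slc6a20 transporter genes, at Vil1, at Edn2 and at Ihh. The strongest up region in the authors' deposited table covered the promoter and exons of Ncald, which encodes the neuronal calcium sensor neurocalcin delta, at chromosome 15, 37455501 to 37461500 (mm10), with a log2 fold change of 2.15 (4.44-fold), an FDR of 3.43e-19 and all 25 windows up. A further up region lay in Ncald at 37428001 to 37434000, with a log2 fold change of 1.46 in the authors' deposited table. A run of 3 up regions on chromosome 9, from 123619501 to 123689000, covered Slc6a20a and Slc6a20b, which encode amino acid transporters of the SLC6 family, with log2 fold changes of 1.43, 1.60 and 1.37 in the authors' deposited table. The promoter and exons at the start of Vil1, which encodes villin, the actin-bundling protein of brush border microvilli, lay in an up region at chromosome 1, 74407001 to 74413000. All 21 of its windows were up, with a log2 fold change of 1.56 and an FDR of 1.87e-08 in the authors' deposited table. Extra Vil1 regulatory DNA from a transgene could also raise reads there and cannot be told apart from a change at the endogenous gene.

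Ihh, the hedgehog ligand made by the gut epithelium, lay in a region at chromosome 1, 74945251 to 74959000, with a log2 fold change of 1.37 in the authors' deposited table (FDR 4.38e-08). Edn2, which encodes the peptide endothelin 2, lay in a region at chromosome 4, 120141001 to 120172000, with 170 of 176 windows up and a log2 fold change of 1.40 in the authors' deposited table. The remaining top up regions in the authors' deposited table were at Dclk3, a doublecortin-like kinase gene (1.35 on the log2 scale), at the serine protease inhibitor genes Serpina3a, Serpina3b and Serpina3c (1.35), at an exon of the integrin gene Itgb6 (1.34) and in an intron of Mageb18 on the X chromosome (1.29). Their FDR values in the authors' deposited table ran from 3.74e-05 at Dclk3 to 0.016 at the Serpina3 genes. Windows counted as up were 65 of 153 at Dclk3, 63 of 162 at the Serpina3 genes, 5 of 5 at Itgb6 and 5 of 7 at Mageb18.

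**Figure D1:**
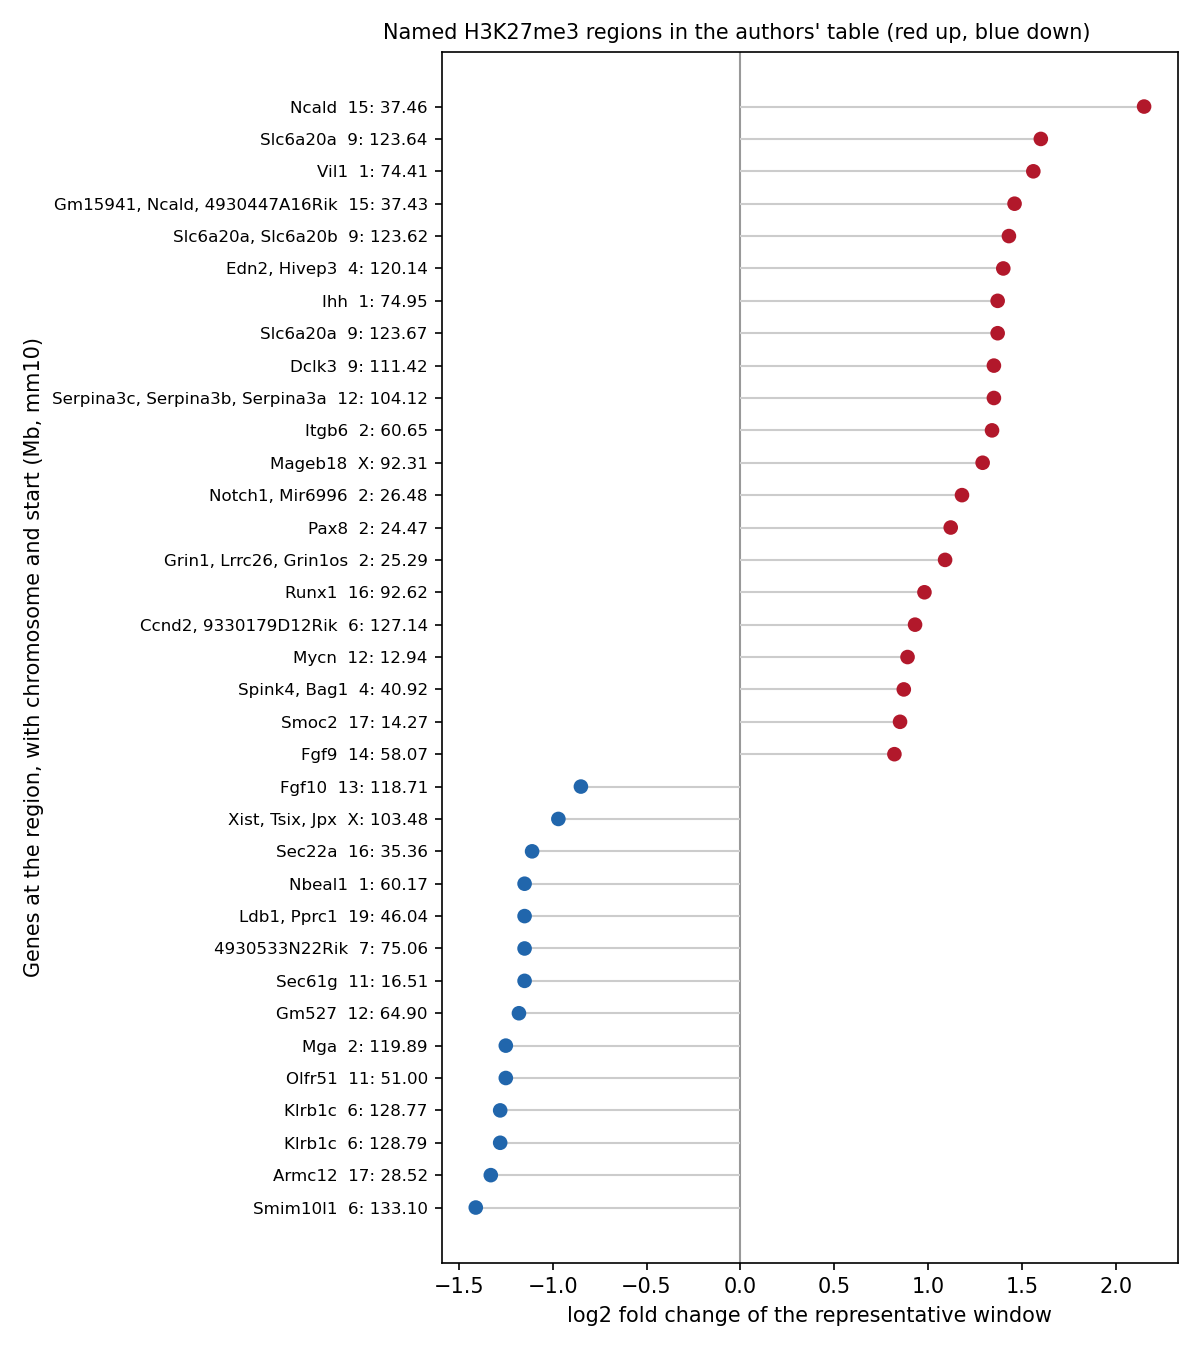
The log2 fold change of the representative window (x axis) of each named H3K27me3 region (y axis, with chromosome and start in Mb, mm10), as given in the authors' deposited table. Red points are up regions and blue points are down regions, and they run from 2.15 at Ncald to -1.41 at Smim10l1; the table gives no error for these values.

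The largest negative changes lay at Smim10l1, Armc12, Klrb1c, Mga and Olfr51. A promoter region of Smim10l1 at chromosome 6, 133100001 to 133102000, had the most negative log2 fold change of the authors' deposited table, -1.41 (FDR 4.64e-08), from a single window. A region at chromosome 17, 28516001 to 28542500, covered Armc12 and had a log2 fold change of -1.33 in the authors' deposited table. The table also assigns this region to the promoter and exons of the glucocorticoid-responsive gene Fkbp5. The RefSeq gene body of Fkbp5 lies 29.9 kb away, and whether the authors' annotation held a longer transcript that reaches the region was not examined. Adjacent regions on chromosome 6, from 128767001 to 128795000, lay at Klrb1c, which encodes the natural killer cell receptor NK1.1, each with a log2 fold change of -1.28 in the authors' deposited table. The promoter of Mga, which encodes a MAX-binding transcription factor of a variant Polycomb complex, lay in a down region at chromosome 2, 119885501 to 119899000, with 49 of 68 windows down and a log2 fold change of -1.25 in the authors' deposited table. Olfr51, an olfactory receptor gene, had -1.25, and Gm527 had -1.18 on the log2 scale in the authors' deposited table. Regions at Sec61g, a subunit of the endoplasmic reticulum translocon, at Nbeal1, at the noncoding gene 4930533N22Rik and at the adjacent genes Ldb1 and Pprc1 each had -1.15, and one at Sec22a had -1.11, in the authors' deposited table. Only 4 of 37 windows were counted as down at Nbeal1 (FDR 0.0443), 12 of 67 at Ldb1 and Pprc1 (FDR 0.0466) and 9 of 85 at Sec22a (FDR 0.0305). At Gm527 15 of 112 windows were down and at Olfr51 7 of 28, against 6 of 8 at Sec61g and 5 of 8 at 4930533N22Rik.

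Of 783 genes in 28 lists of pathways, complexes and cell types fixed before the data were examined, 11 lay at up regions and 4 at down regions. Among 182 developmental transcription factor genes, Pax8 (1.12, FDR 1.61e-04) and Runx1 (0.98, FDR 0.0382) lay at up regions, with log2 fold changes from the authors' deposited table, and none lay at a down region. The Pax8 region had 28 of 28 windows up, and the Runx1 region was an intronic one of 2 windows. Notch1, the receptor that directs crypt progenitors toward the absorptive lineage, was the only one of 22 Notch pathway genes at a changed region. It lay at chromosome 2, 26475001 to 26503500, with 150 of 152 windows up and a log2 fold change of 1.18 (FDR 3.85e-05) in the authors' deposited table. Ihh was the only one of 13 hedgehog pathway genes at a changed region, and Vil1 the only one of 31 enterocyte genes. At Vil1 a technical source was not excluded. Of 16 proliferation genes, Mycn (0.89, FDR 0.0124) and the cyclin gene Ccnd2 (0.93, FDR 0.0343) lay at up regions, with log2 fold changes from the authors' deposited table. A minority of windows was counted as up at both, 26 of 148 at Mycn and 25 of 117 at Ccnd2. The rule for counting is not given, so the other windows need not be unchanged. Smoc2, a marker of intestinal stem cells, was the only one of 20 stem cell genes at a changed region, with a log2 fold change of 0.85 (FDR 0.0327) in the authors' deposited table. Spink4, expressed in goblet cells, was the only one of 17 goblet cell genes, with 90 of 90 windows up and a log2 fold change of 0.87 (FDR 0.0293) in the authors' deposited table. From 28 neuron and glia genes, only Grin1, a glutamate receptor gene, lay at a changed region, with 33 of 124 windows up and 1.09 on the log2 scale (FDR 5.12e-04) in the authors' deposited table.

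The 28 FGF pathway genes included a member in each direction. Fgf9 lay at an up region with a log2 fold change of 0.82 (FDR 0.0279), and Fgf10 at a down region with -0.85 (FDR 0.0207), in the authors' deposited table. From the 14 X-inactivation and escape genes, Xist, Tsix and Jpx shared a down region at X, 103481001 to 103507500, with 66 of 143 windows down and a log2 fold change of -0.97 (FDR 0.0456) in the authors' deposited table. No changed region was assigned to a member of the other 18 lists. These were the 6 H3K27 and H3K9/H4K20 demethylase genes, the 12 PRC2 and 19 PRC1 subunits, 39 Hox genes, 16 genes of regional gut identity, 15 regenerative or fetal-like genes and 7 cyclin-dependent kinase inhibitors. They were also 21 Paneth, 28 enteroendocrine, 16 tuft, 23 immune, 18 stromal and smooth muscle and 14 endothelial cell genes, 48 Wnt and 33 BMP and TGF-beta pathway genes, 42 imprinted genes, 25 antigen presentation and interferon genes and 58 clustered protocadherins. The PRC1 list did not include Mga, which lay at a down region. No list reached the 5 genes set as the minimum for a test, so no list was tested for a direction. The table lists only regions past the threshold, so it cannot say whether a list's genes were over- or under-represented among changed regions. Kdm6a (X, 18160862 to 18279936) and Kdm6b (chromosome 11, 69398508 to 69420367) had 0 changed regions, which says nothing of their deletion, as H3K27me3 does not measure it.

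Up regions outnumbered down regions by 258 to 120, so that 68.3% were up (95% Clopper-Pearson interval 63.3 to 72.9%, two-sided exact binomial p = 1.03e-12 against an even split). Regions are not independent, because 27 pairs of neighbouring regions overlapped and many shared a locus. After regions less than 1 Mb apart were merged, 150 of 236 blocks with a majority were up, or 63.6% (57.1 to 69.7%, exact binomial p = 3.72e-05). The table's FDR and p-values imply 58963 regions tested, of which the changed regions were 0.641%.

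The median log2 fold change in the authors' deposited table was 0.96 in up regions (interquartile range 0.89 to 1.08) and -0.88 in down regions (-1.0 to -0.82). These medians correspond to 1.94-fold and 0.54-fold in the authors' deposited table. The absolute change was larger in up regions by 0.077 in the median (two-sided permutation p = 1.00e-05, the smallest that 100000 permutations can give). The permutation p adjusted over 5 comparisons of up with down regions was 5.00e-05. The difference was not past 0.05 among regions at FDR 0.01 or with 1 region per gene. Only regions past the FDR limit are listed, and the smallest changes listed were 0.77 in up and -0.72 in down regions. The permutations also treat regions as independent, and up regions were wider. The p-value therefore does not show that up changes are larger apart from this selection.

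The X chromosome carried 30 changed regions, 26 up and 4 down. The down region at X, 102760251 to 102770000, had 6 windows up and 3 down of 33, with a log2 fold change of -1.20 in the authors' deposited table. The comparison of X with autosomes was not repeated without it. The share of up regions was 86.7% on X and 66.7% on autosomes, where 232 were up and 116 down (Fisher's exact p = 0.0244, two-sided; 0.0406 adjusted over the 5 comparisons). In 1 Mb blocks the shares were 88.9% and 61.5% (Fisher's exact p = 0.0213). At FDR 0.01, 5 of 5 X regions and 90 of 105 autosomal regions were up (Fisher's exact p = 1). Chromosome 2 carried the most changed regions, 36, of which 28 were up. Set beside the share of the first set of windows that the table's window index allows, which was not tested, it held 9.5% of changed regions and 6.6 to 8.8% of windows. Chromosome 9 held 8.2% and 5.7 to 6.4%, chromosome 4 held 7.9% and 4.8 to 5.8%, chromosome 12 held 5.6% and 3.0 to 4.0%, and chromosome 1 held 6.6% and 5.9 to 6.3%. Shares lay below the windows on X (7.9% against 10.1 to 14.5%), chromosome 14 (1.3% against 2.2 to 3.8%), chromosome 7 (4.8% against 5.1 to 7.1%), chromosome 15 (2.4% against 2.6 to 4.3%) and chromosome 17 (2.9% against 3.0 to 3.9%). The shares of changed regions count every region, including 75 from the second set of windows and each member of a run at 1 locus. On chromosome 14 all 5 changed regions were up, and on chromosome 16 down regions were more numerous, 8 against 4.

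**Figure D2:**
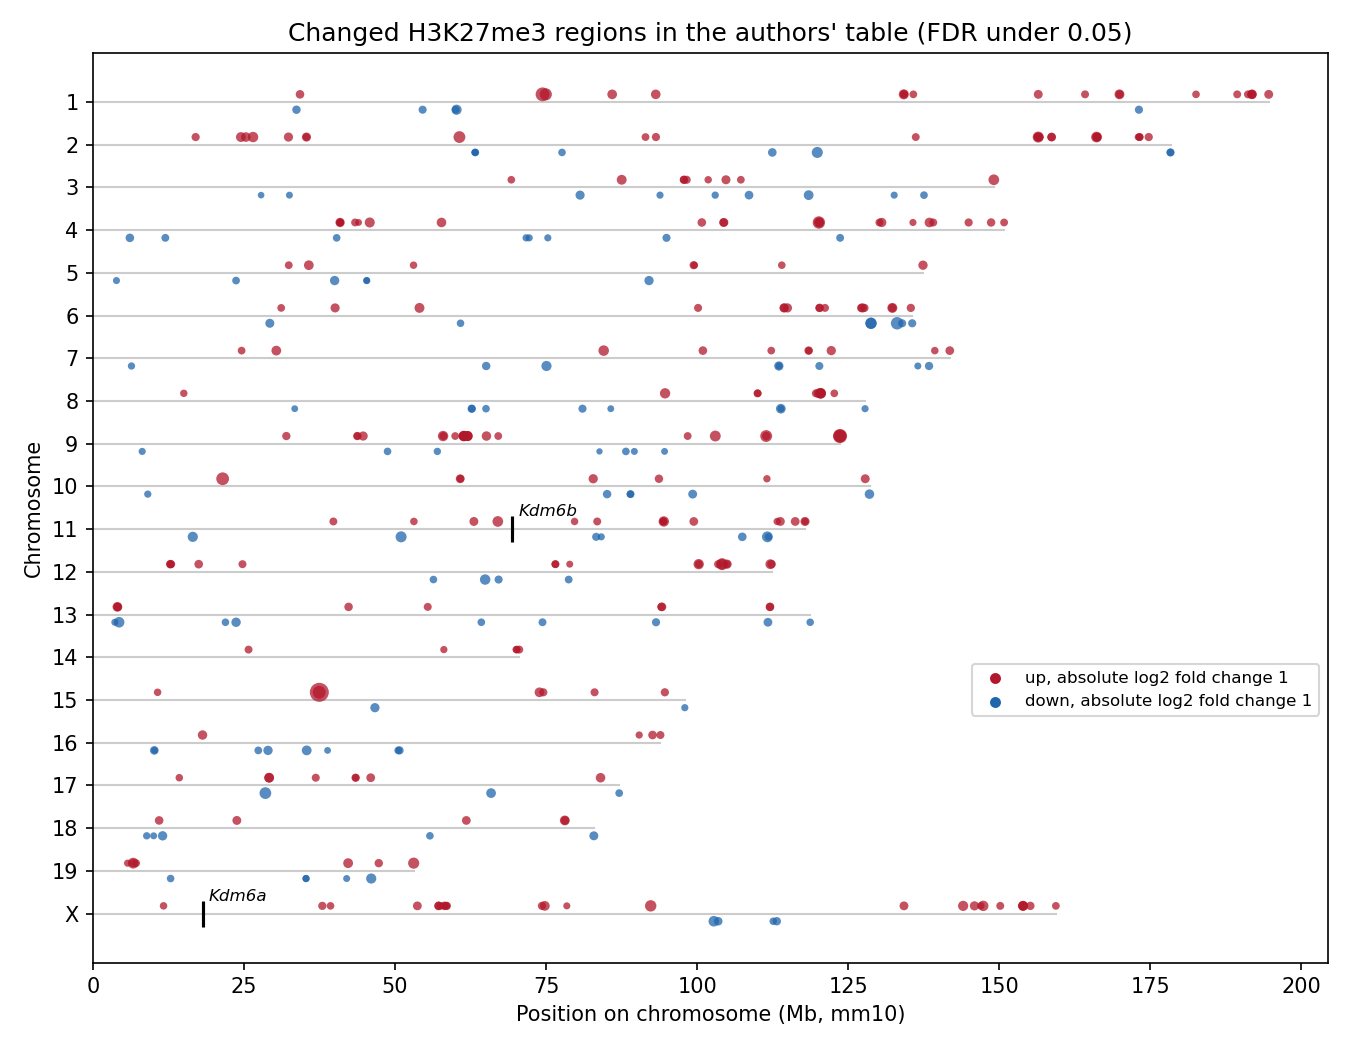
Position of each changed H3K27me3 region on its chromosome (x axis, Mb, mm10; y axis, chromosome), with up regions in red above the line, down regions in blue below it and the point area scaled to the squared log2 fold change of the authors' deposited table. Grey lines end at the last changed region, not at the chromosome end, and black ticks mark Kdm6a and Kdm6b; the X row holds 26 up and 4 down regions.

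A promoter was overlapped by 130 up regions (50.4%) and 59 down regions (49.2%), with no difference detected (Fisher's exact p = 0.912, two-sided; 0.912 adjusted). These shares are per region, not per kb, and up regions were wider. Among regions of at least the median width the shares were 62.0% of up and 66.7% of down regions (Fisher's exact p = 0.71, unadjusted), and among narrower regions 34.3% and 40.7% (Fisher's exact p = 0.366, unadjusted). Gene bodies without a promoter held 60 up and 21 down regions, and 62 up and 34 down regions had no gene within 5 kb. The remaining 6 up and 6 down regions lay within 5 kb of a gene without overlapping it.

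Up regions were wider than down regions, with median widths of 17.25 and 6.0 kb (permutation p = 2.00e-05, two-sided; 5.00e-05 adjusted). With 1 region per 1 Mb block, the one with the lowest FDR, 149 up and 94 down regions had medians of 16 and 6.0 kb (permutation p = 5.00e-05). Among regions wider than 25 kb, 76 were up and 9 down. The widest region was 31500 bp, and neighbouring regions of a long domain abutted or overlapped, as at Tle3 and Epb41l1, so width is capped and understates long domains. Width is also the extent of the merged windows, not of the changed signal. At Dlgap4 15 of 153 windows were counted as up, and at Zbtb16 22 of 177 as down. The wider up regions therefore need not hold wider changes. Across all 378 regions, width and absolute log2 fold change in the authors' deposited table had a Spearman's rho of 0.23 (permutation p = 2.00e-05, 6.00e-05 adjusted over 3 relations) and a Pearson's r of 0.16 (permutation p = 0.00131, 0.00393 adjusted). Within up regions rho was 0.13 (permutation p = 0.0304, 0.0304 adjusted) and r was 0.08 (permutation p = 0.194, 0.194 adjusted). Within down regions rho was 0.28 (permutation p = 0.0019, 0.00285 adjusted) and r was 0.19 (permutation p = 0.0371, 0.0557 adjusted). These correlations run across regions, which are not independent replicates. Each region's value is that of 1 representative window, which in a wide region is taken from more windows. Regions held 1 to 180 windows, and only regions past the FDR limit are listed. The permutations take account of neither, so their p-values do not show that width goes with size of change apart from this selection. At FDR 0.01 rho was 0.11 over 110 regions (permutation p = 0.239). The share of a region's windows counted as changed did not differ detectably between up and down regions, with medians of 72.2% and 64.3% (permutation p = 0.118, 0.147 adjusted).

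**Figure D3:**
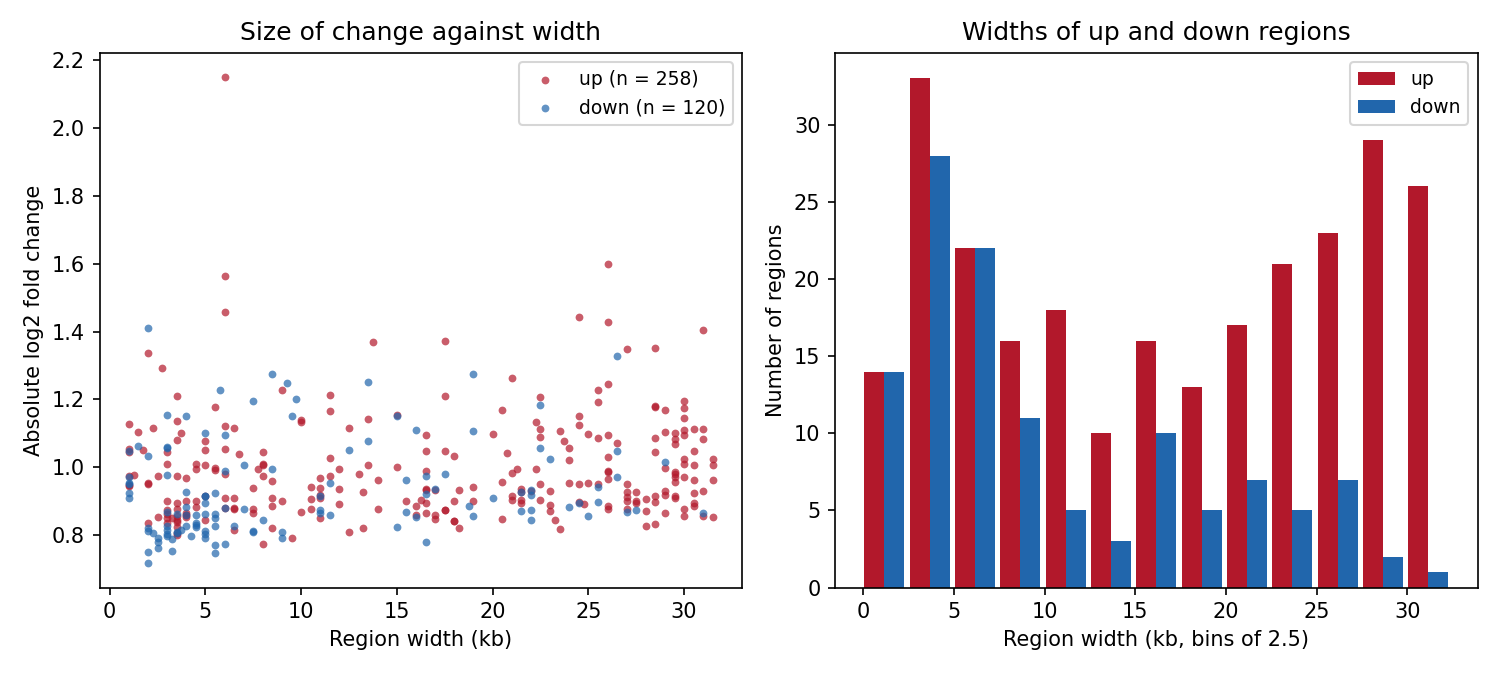
Left, absolute log2 fold change of the authors' deposited table against region width in kb for 258 up (red) and 120 down (blue) regions; right, number of regions per 2.5 kb of width. Up regions have a median width of 17.25 kb and down regions of 6.0 kb.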

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

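The blocks of 100 kb, the narrow regions, the best window, 1 region per 1 Mb block and leaving out gene names far from their reference position were chosen after the data were seen, and the other alternatives before. Of 34 values under alternatives, 19 kept their direction and side of the threshold or stayed within 1.5 times, 5 lost the threshold, 9 counts moved by more than 1.5 times and 1 reversed. The counts fell by construction under stricter limits. At FDR 0.01 there were 110 regions, 95 up and 15 down. With an absolute log2 fold change of at least 1 there were 128, 98 up and 30 down, and by the best window 134, 103 up and 31 down, from the authors' deposited table. The share of up regions was past the threshold in 6 of the alternatives, from 63.5% in 100 kb blocks to 86.4% at FDR 0.01. It was 57.1% among regions narrower than the median width of 13375 bp (exact binomial p = 0.0583) and 79.4% among the others (exact binomial p = 1.50e-16).

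The excess of absolute log2 fold change in up regions of the authors' deposited table went from 0.077 to 0.045 at FDR 0.01 (permutation p = 0.464, with 15 down regions) and to 0.043 with 1 region per gene (permutation p = 0.0547). The difference in up share between X and autosomes went from 20 to 14.3 percentage points at FDR 0.01 (Fisher's exact p = 1), where 5 X regions were left. The rank correlation of width with size of change went from 0.23 to 0.11 at FDR 0.01 (permutation p = 0.239). For the size and width results the cause was not tested. With 1 region per 1 Mb block, the difference between up and down regions in the share at promoters went from 1.2 to -3.0 percentage points, neither detectably different from 0 (Fisher's exact p = 0.912 and 0.693), and the cause was not tested. The size, width and correlation results kept their direction and threshold with 1 region per block. No gene list reached the 5 members needed for a test under any of the 3 alternatives run for the lists, so their agreement says nothing of stability.

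No paired analysis was possible because the table holds no value per sample. For the same reason DESeq2 in place of edgeR, other size factors, no filter on low counts, a replicate block and leaving out each replicate were not run. FDR 0.1 was not run because the table ends at 0.0498, and promoters of 1 kb were not run because gene strand was not used here. Depth per library is unknown, so regions outside the table cannot be called unchanged.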

Other observations

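The comparisons in 1 Mb blocks, among the wider regions and at FDR 0.01 were planned before the data were examined, while the other tests in this part, and the genes named here that the report's own text does not describe with values, were chosen after the table was seen. Several loci carried runs of up regions. Epb41l1, which encodes a membrane skeleton protein, was assigned 5 up regions, with log2 fold changes of 0.87 to 1.25 in the authors' deposited table. Sulf2, which encodes a heparan sulfate sulfatase, and Tle3, which encodes a Groucho family corepressor, were each assigned 3 regions of a run of 5 up regions spaced within 100 kb, with log2 fold changes over the runs of 0.89 to 1.21 and 0.86 to 1.19 in the authors' deposited table. Gse1 had a run of 4 (0.99 to 1.21) and the membrane progestin receptor gene Paqr5 a run of 3 (1.06 to 1.15) in the authors' deposited table. All 3 endothelin genes lay at up regions, with log2 fold changes of 1.40 at Edn2, 0.96 at Edn1 and 0.93 at Edn3 in the authors' deposited table. Their FDR values there were 3.47e-07, 0.0461 and 0.0154, and at Edn1 14 of 66 windows were counted as up. Other up regions of the authors' deposited table lay at Mep1a, a brush border metalloprotease (0.84), the interleukin 22 receptor gene Il22ra1 (0.80) and the mucin gene Muc5ac (0.99). The FDR was 0.0297 at this Mep1a region, 0.0436 at Il22ra1 and 0.0491 at Muc5ac, where 35 of 146 windows were counted as up.

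The only run of at least 3 down regions lay on chromosome 2 from 63181001 to 63281000, with log2 fold changes of -0.88 to -0.75 in the authors' deposited table. Its region of -0.75 was assigned to the potassium channel gene Kcnh7 in the authors' deposited table, and the others had no gene within 5 kb. Far1 had 2 down regions, of -1.05 and -0.83 on the log2 scale in the authors' deposited table. A down region also lay at Dusp6, a phosphatase acting on ERK (-1.01 on the log2 scale), in the authors' deposited table. An up region of chromosome 10 starting at 21442501 had a log2 fold change of 1.44 in the authors' deposited table and no gene within 5 kb. Within 100 kb, 79 of 79 neighbouring pairs of changed regions shared a direction, against at most 60 in 10000 shuffles. This argues against directions set independently from region to region. However, 27 of these pairs overlapped and so share reads, and others can be pieces of 1 long domain, as width is capped. The count therefore does not show that separate loci share a direction. Genes named Zfp lay at 6 down regions and 1 up region. Of 5 families of gene symbols tested, only Zfp passed, with a Fisher's exact p of 0.00454 (0.0227 adjusted over the 5), but the name covers unrelated zinc finger genes and the family was noticed in the same table.

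The excess of up regions has several candidate sources. Repeated counting of a locus alone is argued against, as 63.6% of 1 Mb blocks were up (57.1 to 69.7%), and so is strain DNA linked to the targeted alleles as the main source, as 3 of 378 changed regions lay within 10 Mb of Kdm6a or Kdm6b. Whether narrow regions favour neither direction stays open: 57.1% of them were up (49.8 to 64.3%), against 79.4% of the wider ones, and the difference between the width classes had a Fisher's exact p of 5.04e-06. With 1 region per 1 Mb block, 51.9% of narrow and 72.3% of wider regions were up (Fisher's exact p = 0.00147). A gain of H3K27me3 after loss of its demethylases would be consistent with the excess if up means higher in DKO, but the table does not name its reference, and the authors' normalization could not be examined.

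The Vil1 region is a candidate for a technical source. Vil1 regulatory DNA is widely used to drive Cre recombinase in gut epithelium, and extra copies of Vil1 regulatory DNA from a Vil1-driven transgene could raise reads there if the groups differed in carrying it. The region runs from 2.38 kb before the reference start of Vil1 to 3.62 kb after it, 100% of its windows were up, and the nearest other changed region, at Ihh, was 532 kb away. A transgene and a change of H3K27me3 at the endogenous gene, a gain only if up means higher in DKO, cannot be told apart. The labels used here do not give the Cre driver or whether controls carried it. Every window was also up in 34 of the 244 other up regions with at least 5 windows, so a fully changed region is not specific to Vil1.

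Changed regions on X were mostly up. Unequal X dosage between the groups as a whole would shift most X windows together. X held 7.9% of changed regions (5.4 to 11.1%), below the 20.3% that 2 times its lowest share of windows would give. This sets merged regions of both window sets against windows of the first set, and the multiple was chosen after the table was seen. The comparison therefore cannot exclude unequal dosage. A single sample of the other sex stays open, with 86.7% of X regions up, because it would move a group's mean little and the table holds no value per sample. A chance excess stays open too: the 1 Mb blocks gave a Fisher's exact p of 0.0213, but they re-test the same excess, and at FDR 0.01, with 5 X regions, the Fisher's exact p was 1. The down region at Xist, Tsix and Jpx lies against the direction of most X regions, with a log2 fold change of -0.97 in the authors' deposited table. Its FDR there was 0.0456, with 66 of 143 windows counted as down, and it does not decide between these explanations.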
